A study of Mus musculus with 5 samples.

How the data were processed

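The data were 5 expression arrays of soleus, a slow, postural calf muscle, from C57Bl/6 mice. Per the labels, each array received 3 microgram of total RNA, isolated with a column kit from frozen muscle sections. The 5 arrays were hybridised with RNA of reloaded mice, day 7 according to the series title, and their titles are numbered 1, 3, 4, 5 and 6, here mice 1, 3, 4, 5 and 6. The labels used here give this group alone, so no unloaded or untreated muscle was analysed here and no difference between conditions was tested.

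The values deposited by the authors are linear array intensities for 223 probes. The background correction, scanner and scaling behind them are not given in the sources used here. Values slightly below 0, such as background subtraction gives, occur on every array. Column medians from 0.013 to 0.0338 and column totals from 70.8 to 137 show no scaling to a common median or total. The intensities are therefore in arbitrary units of unknown reference. Probe identifiers were paired with genes through the platform annotation, and symbols were updated through the gene identifier to the GRCm38.p6 gene table. Of the 223 probes, 205 had 1 gene symbol, none had several, and 18 had no entry and are unnamed here. Of the 205, 204 were found in the mouse table. The exception, POLB, is listed with a human gene record. Fn1 and Igf1 each had 2 probes, whose log2 values were averaged for gene-level results. No genome was given, so positions in genes are not reported.

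A probe was kept if it was above 0 on all 5 arrays, which held for 147 probes. The rule fixed before the data were examined took the deposited values as normalised only if the column medians lay within 10% of each other. They did not, so log2 intensities of the kept probes were quantile normalised between arrays. A probe that is the brightest on every array gets the same value on each by construction. This applied to 1 unnamed probe, which was left out of the tests once this was seen, which leaves 146 probes and 138 genes. For the same reason bright genes take few distinct values, and their CVs are also given under other scalings. Signals of different probes depend on the probe and are not compared with each other. For arrays, precision is limited by their number, here 5. The labels call each sample a reloaded mouse without describing how animals were sampled, so the results describe only these 5 samples. The p-values set a probe against other probes, or a list against random lists. They do not measure how results would vary in other mice.

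Means, SDs and coefficients of variation (CV, the SD as a percentage of the mean) were computed on the linear normalised scale. With no repeat arrays, SDs and CVs between mice hold measurement noise as well as differences between animals. Whether a probe varied more or less between mice than probes of like signal was tested with limma 3.58.1 in R 4.3.3: the log2 variance was set against a robust trend in mean signal (fitFDistRobustly, statmod 1.5.0), with the F distribution's tail probability and Benjamini-Hochberg adjustment at 0.05. The script was tested on simulated data. With 3 of 146 probes given a 5-fold larger SD and all others on the trend, 90.0% of the 3 were recovered. With the spread of variances fitted to the real data and 30 probes changed, 0.2% were recovered at a 2-fold and 0.0667% at a 3-fold larger SD, so a count of 0 does not show that genes varied alike.

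Before the data were examined, 17 gene lists were fixed, among them markers of immune, fat, nerve, blood and endothelial cells. A gene may be in several lists. Lists with at least 4 measured genes, 10 in all, were tested by 2 measures: the median of the members' log2 SD relative to the trend (two-sided), and the co-variation, which is the SD over the 5 mice of the members' mean log2 deviation from their own means (one-sided, larger). Each was compared with 10000 random lists of the same size matched on 3 classes of mean signal, and adjusted over the 10 lists. These random-list permutations describe these arrays and treat genes as independent. Simulation of the 6-gene matrix list recovered a shared log2 SD of 0.3 in 25.0% and of 0.6 in 77.5% of 40 data sets. No correlation across samples is given, as the samples are too few.

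Named genes followed a fixed rule. In each tested list, they were the gene with the highest mean signal and the gene with the largest CV. The rule also took the 5 widest and the 5 narrowest spreads relative to the trend, over named probes above 0 on all 5 arrays. Other genes of the fixed lists that are named were chosen after their values were seen. Alternatives were values as deposited, scaling to the array median or total, leaving out the dimmest 25% of probes, keeping probes at or below 0 at a floor, leaving out each mouse, other variance models and other list weightings. Scaling to the 28S ribosomal RNA probe was added after seeing the data. Figures were drawn with matplotlib 3.10.9.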

Results

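Gene expression was measured on a 223-probe array in the soleus of 5 C57Bl/6 mice at day 7 of reloading, when the muscle again bore weight. The comparison the design allows is between the 5 mice of this group: which of the muscle, vascular and matrix genes on the array gave a signal, and how far the signal of each gene differed from mouse to mouse. The total deposited signal was 137 on the array of mouse 1, 84.7 for mouse 3, 70.8 for mouse 4, 81.7 for mouse 5 and 131 for mouse 6. A single unnamed probe held between 35.4% and 46.0% of the total. Probes at or below 0 numbered 53, 36, 20, 59 and 34 on the arrays of mice 1, 3, 4, 5 and 6. Levels below are quantile-normalised signals in arbitrary units, given as mean ± SD over 5 mice.

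Structural and energy-metabolism genes of the muscle fibre gave a signal in every mouse. All 147 probes above 0 on all 5 arrays were taken as measured, 59 probes were above 0 on some arrays, and 17 were at or below 0 on all. The slow myosin heavy chain Myh7 and the fast chains Myh1, Myh2 and Myh4 were all measured, as were all 5 genes of the citrate cycle and respiratory chain list, 10 of 11 genes of glucose uptake, glycolysis and glycogen, and 8 of 9 genes of fatty acid uptake and oxidation. In the last list the exception was Lipe, hormone-sensitive lipase, which was at or below 0 in every mouse. Of the 5 myogenesis genes on the array, Des (desmin), Myf6 and Myog were above 0 in all mice, Myod1 in some and Myf5 in none. Il1b and Il6, the 2 members of the fixed immune cell list on the array, were at or below 0 in all 5 mice. Other genes expressed in immune cells, named after their values were seen, lay on both sides: Csf2ra and Csf2rb2 were above 0 in all 5 mice, Csf2rb and Btk in 4, Mmp12 in 1, and Csf3r, Mmp8 and Mmp9 in none. A value at or below 0 bounds a signal only by the background, and does not show that the transcript was absent.

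Myosin heavy chain signals were 4.56 ± 0.876 for Myh7, 2.07 ± 0.239 for Myh2, 1.48 ± 0.256 for Myh1 and 0.517 ± 0.0924 for Myh4 (SD, n = 5). Their CVs were 19.2%, 11.5%, 17.3% and 17.9%. With each array scaled to its median instead, the CVs were 16.2% for Myh7, 26.3% for Myh2, 31.2% for Myh1 and 20.6% for Myh4. Scaled to the total, that of Myh4 was 11.2%. Myoglobin (Mb), the oxygen-binding protein of red muscle, was at 3.27 ± 0.683, and desmin at 1.14 ± 0.193. The SD of Mb comes from tied ranks after quantile normalisation, with 4.50 in mouse 5 and 2.97 in each of the other mice. As deposited, Mb was at 3.53 in mouse 5, below 3.98 in mouse 1 and 3.80 in mouse 6. The CVs of Mb and desmin, 20.9% and 17.0%, were 27.5% and 27.1% with median scaling and 24.9% and 33.0% as deposited. Of the other stress and redox genes, Nos2 was at 0.0182 ± 0.00924 and Hmox1 at 0.0217 ± 0.00259. Their CVs of 50.9% and 11.9% were 41.3% and 44.3% as deposited. Dgat1, the measured gene of lipid synthesis, was at 0.0110 ± 0.00383. The myosin chains are similar in sequence, and cross-hybridisation between them was not tested.

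Spread between mice was moderate and was wider for dim probes. No sample was measured on a repeat array, so this spread includes measurement noise. That noise cannot be told apart from differences between animals. The median CV over 146 probes was 33.1%, with quartiles of 19.3% and 44.3%. By signal, it was 44.4% for the dimmest probes, 34.0% for the middle class and 20.9% for the brightest. No probe was called more variable than its signal predicts (limma, smallest adjusted p = 0.89), and none less variable (smallest adjusted p = 0.34). At an unadjusted p below 0.05 (limma), 7 probes were wider and 8 narrower, against 7.3 expected by chance for each. The trend and the distribution were fitted to these same 146 probes. Counts near 7.3 are therefore largely set by the fit and say nothing about how alike the genes were. With values as deposited, 2 probes, Thbs2 and Csf2rb2, were called more variable. Simulated SDs 2- to 5-fold larger in 30 of 146 probes were almost never recovered, also with the other probes on the trend. A 5-fold SD in only 3 probes, with the others on the trend, was recovered in 90.0%. The count of 0 therefore does not show that genes varied alike.

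**Figure D1:**
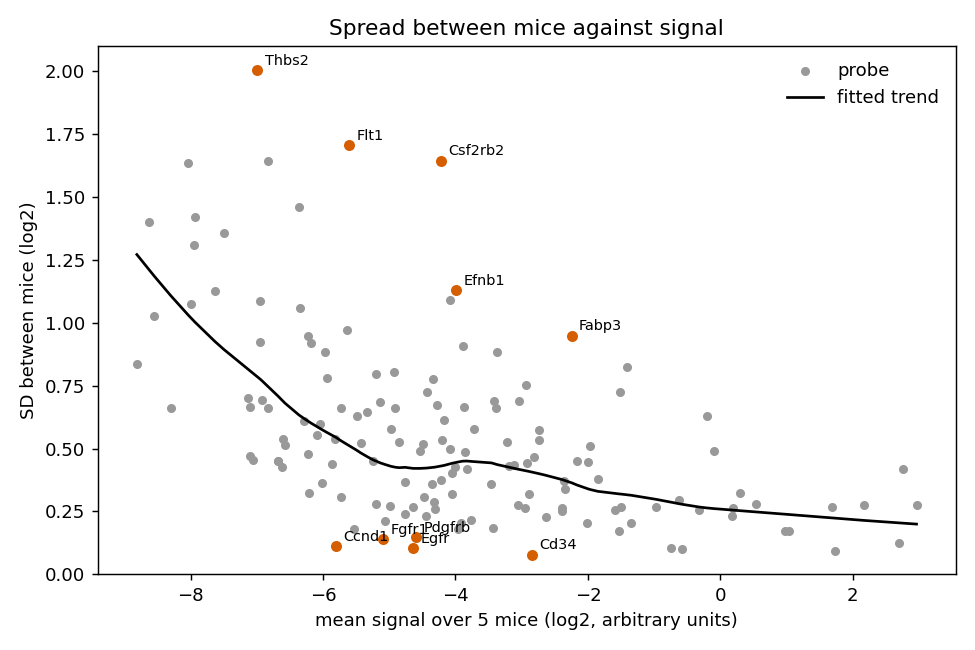
SD between the 5 mice (log2) of each of 146 probes against its mean quantile-normalised signal (log2, arbitrary units), with the fitted trend as a line. Orange points are the 5 widest and the 5 narrowest named genes relative to the trend, such as Csf2rb2 with an SD of 1.65 and Cd34 with 0.08.

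Among named genes above 0 on all 5 arrays, the 5 with the widest spread relative to the trend were Csf2rb2, Flt1, Fabp3, Thbs2 and Efnb1. Genes at or below 0 in any mouse were not ranked. An example is Lama3, whose deposited values ran from -0.0055 in mouse 1 to 0.317 in mouse 6. Csf2rb2, a beta subunit of the interleukin-3 receptor, was at 0.0737 ± 0.0395, with an SD 3.82 times the trend. Csf2rb, also on the array, is a close paralogue, so the source of the signal is uncertain. Flt1, a VEGF receptor of endothelium, was at 0.0288 ± 0.0164. In both genes the value of mouse 1 was far below the others: 0.00712 against 0.0767 to 0.109 for Csf2rb2, and 0.00256 against 0.0253 to 0.0461 for Flt1. The deposited values of mouse 1 were 0.0087 and 0.003, on an array whose values went down to -0.0168. Both low values are thus near the background, and their log2 distance from the other mice is uncertain. The CVs of Csf2rb2 and Flt1, 53.7% and 57.1%, were 17.3% and 24.9% without mouse 1. Fabp3, the fatty acid binding protein of heart and muscle, ranged from 0.0973 in mouse 3 to 0.395 in mouse 1 (CV 57.0%). Thbs2 (thrombospondin 2, a matrix protein) had a CV of 75.2%, which was 47.1% without mouse 5, whose deposited value was 0.0001. The ephrin Efnb1 ranged from 0.0236 in mouse 1 to 0.178 in mouse 3.

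The narrowest genes relative to the trend were Cd34, a marker of endothelial and progenitor cells, the cyclin Ccnd1, and the growth factor receptors Egfr, Fgfr1 and Pdgfrb. Their CVs were 5.43%, 7.80%, 7.14%, 9.39% and 10.3%. These low values depended on the scaling, though little for Fgfr1 and Pdgfrb with median scaling. In the same order, the CVs were 12.1%, 21.4%, 11.9%, 9.04% and 11.1% with median scaling. Scaled to the total, they were 26.3%, 29.9%, 20.7%, 21.9% and 13.1%. As deposited, where differences in signal between whole arrays add to the CV, they were 38.5%, 46.4%, 35.2%, 36.7% and 23.3%. Leaving out mouse 1 gave 3.49% for Cd34, and leaving out mouse 1 or mouse 3 gave 3.59% or 5.95% for Fgfr1. None of the 5 passed the limma test after adjustment. For 21 of the 28 genes named by the fixed rule the CV moved by over 1.5 times in at least 1 alternative setting.

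The spread of carbohydrate and respiratory genes did not pass the list test, and their CVs depended on the scaling. Over the 10 glucose and glycolysis genes the CV ran from 8.37% to 33.2%, with a median of 20.6%. As deposited it ran from 27.7% for Pdha1 to 65.8% for Hk1. Their median log2 ratio of SD to trend was -0.61, at percentile 0.87 of 10000 matched random lists (permutation p = 0.018, adjusted p = 0.18 over 10 lists), so the difference did not pass the threshold. Gapdh, a glycolytic enzyme that is also a control gene, was at 7.91 ± 1.43 with a CV of 18.1%, which was 11.3% without mouse 3, 29.9% with median scaling and 39.0% as deposited. Slc2a4, the insulin-responsive glucose transporter, had a CV of 33.2% around 0.148, or 19.3% scaled to the total. It was the largest of the list in the main setting, while Hk1 (hexokinase 1) had the largest as deposited and with scaling to the median or total. The 5 citrate cycle and respiratory chain genes had a median CV of 14.3%. As deposited, their CVs ran from 28.6% for Cox4i1 to 36.5% for Cox8a. Cox6a2, the muscle form of a cytochrome oxidase subunit, was at 3.34 ± 0.207 with a CV of 6.20%, against 20.2% with median scaling. Mdh2, mitochondrial malate dehydrogenase, was at 0.201 ± 0.0492, and its CV of 24.5% was 15.6% without mouse 1 and 11.2% scaled to the total. The adjusted p for spread of this list was 0.81.

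Fatty acid genes deviated together in mice 4 and 6, which did not pass the test in the main setting. All 8 measured genes were below their own 5-mouse mean in mouse 6, with a mean deviation of -0.47 on the log2 scale. This held with median scaling, but 7 of the 8 were below it when scaled to the total, and 7 of the 8 lay above it as deposited. In mouse 4 all 8 were above it, at 0.36, or 7 of the 8 as deposited and with median scaling. Mice 1, 3 and 5 were at 0.05, -0.12 and 0.18. As deposited, the list was at 0.18 in mouse 6, where the median gene of that array lay 0.58 above its mean. The SD over mice of the list's mean was 0.31, at percentile 94.4 of random lists (permutation p = 0.056, adjusted p = 0.29). Without mouse 1 the adjusted p was 0.0088, and with each gene scaled by its own SD it was 0.017, within a range of 0.0088 to 0.99 over all alternatives. The spread of the list passed the threshold only as deposited, where it was narrower than that of random lists (permutation test, adjusted p = 0.0020, range 0.0020 to 0.95). Cd36, the fatty acid translocase, was at 0.260 ± 0.0809 over the mice. Lpl (lipoprotein lipase), Fabp4, Acadl, Acadm and Hadh of beta-oxidation and the carnitine transferase Cpt1b were lowest in mouse 6, but scaled to the total only 1 of the 8 genes was lowest there, with 5 lowest in mouse 1, and as deposited 0 were. Fabp4, a marker of fat cells and the only measured gene of the fat, nerve and blood list, was at 0.162 ± 0.0248.

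**Figure D2:**
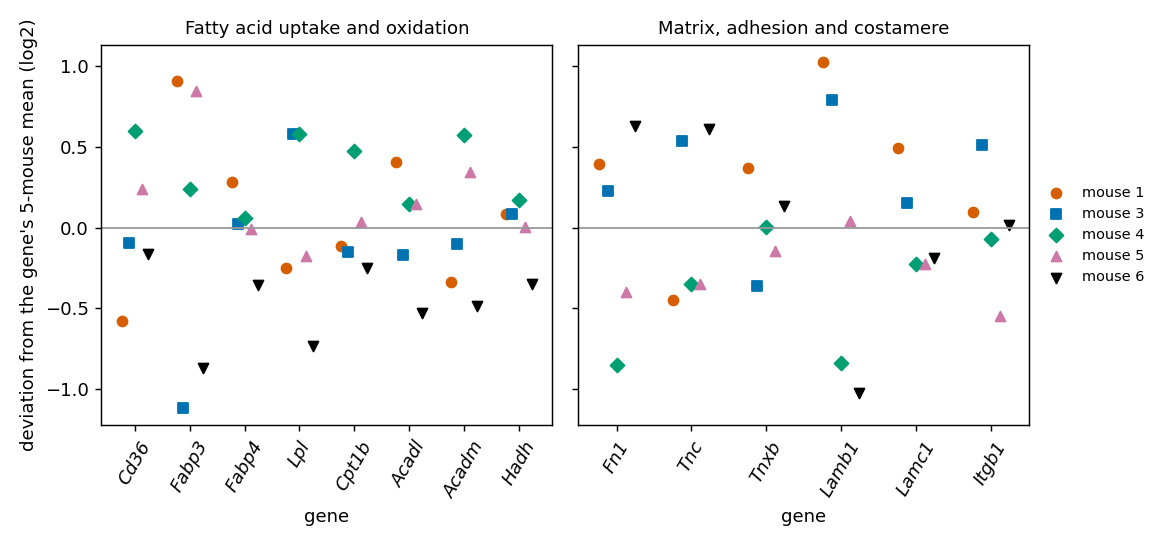
Deviation of each gene from its own 5-mouse mean (log2) for the 8 fatty acid genes (left) and the 6 matrix, adhesion and costamere genes (right), 1 symbol per mouse. Mouse 6 lies below 0 for all 8 fatty acid genes, though above it for 7 of them as deposited and for 1 when scaled to the total, and mouse 5 lies below 0 for 5 of the 6 matrix genes.

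The matrix list and the list of protein breakdown and matrix proteolysis had higher mean deviations in mice 1 and 3 than in mice 4 and 5. Neither list passed the test, and mouse 1 was no longer above mouse 4 in the matrix list when scaled to the array total. The 6-gene matrix, adhesion and costamere list was at 0.32 in mouse 1, 0.31 in mouse 3, -0.39 in mouse 4, -0.27 in mouse 5 and 0.03 in mouse 6 (percentile 92.1, permutation p = 0.079, adjusted p = 0.29). Scaled to the array total, mouse 1 was at 0.03 and mouse 4 at 0.04. Fn1 (fibronectin) ranged from 0.160 in mouse 4 to 0.444 in mouse 6, with a CV of 37.9%, or 58.4% as deposited. Its 2 probes had CVs of 39.4% and 46.0%, and both were lowest in mouse 4. They differed in the highest mouse. The first was highest in mouse 1, at 0.150 against 0.121 in mouse 6. The second was highest in mouse 6, at 1.64 against 0.954 in mice 1 and 3. The laminin chain Lamb1 had the largest CV, at 59.1% around a dim signal of 0.00946, and Tnc (tenascin C), a matrix protein of loaded and injured muscle, was at 0.113 ± 0.0425. The 8 genes of protein breakdown and matrix proteolysis stood at 0.34, 0.15, -0.37, -0.17 and 0.05 in mice 1, 3, 4, 5 and 6 (permutation test, adjusted p = 0.48), with mouse 1 at -0.01 when scaled to the total. Of the 8, 5 lay above their own mean in mouse 1, 3 in mouse 3, 1 in mouse 4 and 3 in mouse 5. In mouse 1 the highest were Ctsh at 1.16 and Cast at 0.97, and the lowest was Plau at -1.07. The list's mean therefore does not show that its matrix proteolysis genes rose as a group. Mmp2, a gelatinase, ranged from 0.0191 in mouse 5 to 0.0694 in mouse 3, and the protease inhibitor Timp2 was at 0.201 ± 0.0521.

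Vascular genes were measured for 11 of the 14 list members on the array and had a median CV of 48.9%. Some members were dim, such as Angpt1 at 0.00251 and Nos3 at 0.00351. Relative to the trend, the list's spread was at percentile 74.4 of matched random lists (permutation p = 0.56, adjusted p = 0.93). It was thus not called wider than that of genes of like signal. Vegfc and Edn1 were above 0 on some arrays, and Vhl on none. The list's mean deviation was 0.32 in mouse 4 and 0.34 in mouse 5, and -0.21, -0.36 and -0.09 in mice 1, 3 and 6 (percentile 91.3, permutation p = 0.087, adjusted p = 0.29). The value of mouse 5 was -0.19 with median scaling, -0.27 scaled to the total and -0.53 as deposited, and that of mouse 6 was above 0 in these settings. Pecam1, an endothelial adhesion molecule, was at 0.158 ± 0.0568. The angiopoietin receptor Tek had a CV of 81.3% at a signal of 0.00645, and 52.6% without mouse 4.

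**Figure D3:**
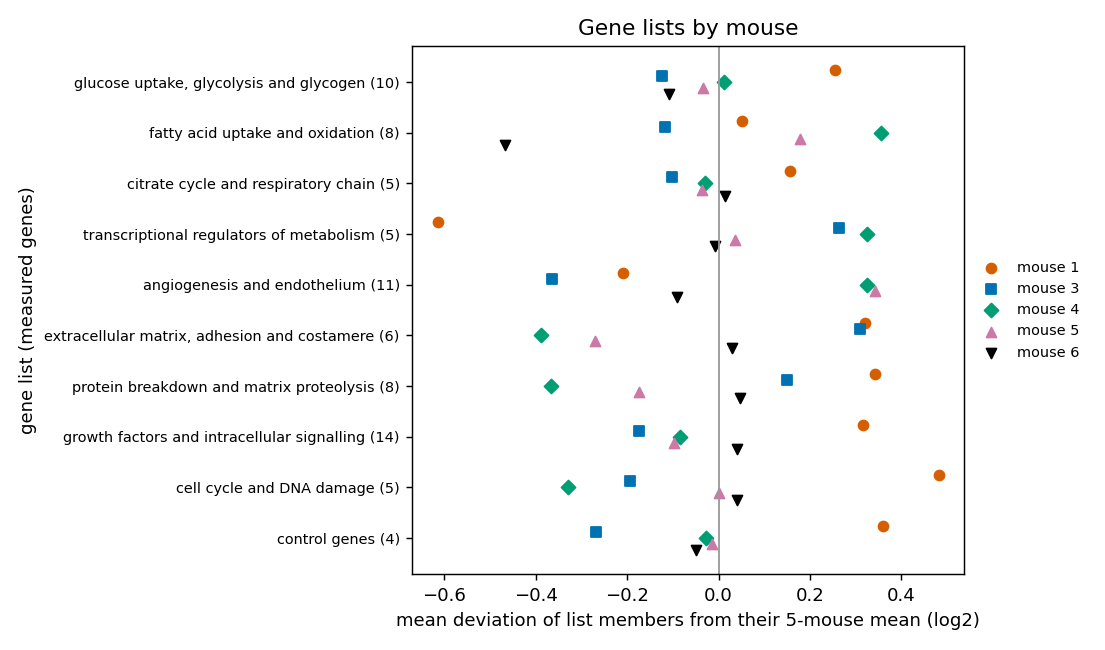
Mean log2 deviation of the measured genes of each of 10 fixed lists from their own 5-mouse means, 1 symbol per mouse, with the number of genes in brackets. Mouse 1 lies at a mean of -0.62 for the list of transcriptional regulators, which also holds the uncoupling protein Ucp3 (at 0.44). It lies below 0 there also as deposited and when scaled to the median or total. Mouse 6 lies at -0.47 for fatty acid genes, but at 0.18 as deposited.

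In the remaining tested lists the adjusted p was at least 0.48 for co-variation and 0.93 for spread. The 5 measured genes of the list of transcriptional regulators of metabolism had a mean deviation of -0.62 in mouse 1. Ppara was at -1.61, Arnt at -1.11, Mef2a at -0.77 and Mef2c at -0.03. Ucp3, which the list also holds, is an uncoupling protein and not a transcriptional regulator, and was at 0.44. As deposited and with median scaling, 2 of the 5 lay above their mean there. Among them Mef2c, a muscle transcription factor, was at 0.358 ± 0.0670, and Ppara, a nuclear receptor that controls fatty acid oxidation, had a CV of 51.8%, which was 30.7% without mouse 1. Of the growth factor and signalling genes, Igf2 was at 0.347 ± 0.0412 (CV 11.9%, or 32.7% as deposited), while Fgf2 had a CV of 70.0% around a dim 0.00554. The 2 Igf1 probes, at 0.137 ± 0.0417 and 0.194 ± 0.0342, had CVs of 30.4% and 17.7%, and the CV of the gene, 23.4%, was 46.7% as deposited. In the cell cycle list, Cdk4 was at 0.0469 ± 0.0167, and the cell cycle inhibitor Cdkn1a reached 0.0563 in mouse 1 against 0.00309 to 0.00984 in the others, so that its CV of 139% was 50.5% without mouse 1. Of the control genes, Ywhaz had a CV of 53.9%, which was 22.2% without mouse 1 and 31.8% scaled to the total. No gene of the fixed lists was called more variable when adjusted over the list alone, nor over all genes tested (limma). At an unadjusted p below 0.05, 3 of their 85 measured genes were wider and 5 narrower than the trend.

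The arrays ranked the probes alike, with the array of mouse 1 furthest from the rest. Across the 147 measured probes, Spearman's rho was 0.949 to 0.979 for the 6 pairs without mouse 1 and 0.864 to 0.890 for the 4 pairs with it. Pearson's r of log2 signals was 0.948 to 0.973 and 0.896 to 0.915. These correlations are across probes, which are not independent replicates. The median absolute log2 difference between 2 arrays ran from 0.24 to 0.42 without mouse 1 and from 0.53 to 0.72 with it. No array was a copy of another.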

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

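Of 43 sets of 5 values checked for a sample far from the others (28 named genes, 10 lists and 5 array measures), 4 met Dixon's criterion. Chance gives about 1 in 20 for sets of independent, normally distributed values not chosen by their spread. The mean rank correlations of the arrays share pairs of arrays and are not independent, so the rate does not hold for them. Many of the 28 genes were named for a wide or narrow spread, so the rate does not hold for these genes either. The number of sets found therefore has no chance value here. In the weighing of the array of mouse 1, the test of position was settled only after its result was seen.

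The mean rank correlation of mouse 1 with the other arrays was 0.878, against 0.941 to 0.947 for the others (gap of 0.920 of the range). In Csf2rb2 (0.872 of the range) and Flt1 (0.792) the same mouse was far below the rest, with deposited values near the background (0.0087 and 0.003). The gaps stayed above the critical 0.71 with scaling to the median (0.846 and 0.755) or the total (0.794 and 0.716), but with values as deposited they were 0.647 and 0.655. In Cox6a2 mouse 5 stood at 2.97 against 3.43 for each of the other mice, a gap of 1 (the whole range). That gap comes from tied ranks after quantile normalisation, since it was 0.477 with median scaling and 0.155 as deposited.

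For the array of mouse 1, an explanation by background subtraction, which acts on dim probes, was tested by signal. Its mean log2 difference from the other arrays exceeded the largest of theirs by 0.43 in the 48 dimmest probes and by 0.038 in the 49 brightest, where the SD of the other 4 arrays was 0.044. The excess therefore lay mostly in dim probes, and whether any of it remains in bright ones stays open. An effect of position on the array, reading the probe identifiers as grid positions, also could not be excluded: deviations of adjacent spots of mouse 1 correlated at 0.176, above the 95th percentile of 0.0892 for shuffled spots, but another array reached 0.169, and adjacent spots hold related genes. The design has 1 group, so no biological explanation was tested.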

How the results depend on the processing

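The number of measured probes, 147, was 145 with the limit at each array's doubled lowest positive value. That limit lay close to 0, while values went down to -0.0041 in mouse 4 and -0.0168 in mouse 1. It therefore does not test whether the measured probes rise above the background. The number was 147 to 162 when a mouse was left out. The median CV of 33.1% was 45.2% for values as deposited and 49.6% when scaled to 28S ribosomal RNA, the setting added after seeing the data. It ran from 24.5% to 35.3% when a mouse was left out, the lowest value being without mouse 1. The median rank correlation between arrays, 0.955, ran from 0.920 to 0.956 when a mouse was left out. The count of more variable probes, 0, became 2 (Thbs2 and Csf2rb2) as deposited and 2 when scaled to 28S ribosomal RNA. It stayed at 0 in the other settings tried, while the count of less variable probes was 0 in all of them (limma). The count of lists past the threshold for spread, 0, was 1 as deposited (fatty acid genes, narrower, adjusted p = 0.0020, range over the alternatives 0.0020 to 0.95). The count for co-variation was 0 to 1 when a mouse was left out and 1 with members scaled by their SD, in both cases the fatty acid list (adjusted p 0.0088 to 0.99 over the alternatives). Of 129 list values for spread, 128 stayed on their side of the threshold, as did 137 of 139 for co-variation. Without the dimmest 25% of probes the cell cycle list had too few genes for a test. None of these spreads was called in the main setting, and 30 of the 129 changed sign. Of the 28 named genes, 21 had a CV that moved by over 1.5 times in some setting, and 11 when 1 mouse was left out. All 10 of the brightest genes took repeated values after quantile normalisation, and their median CV of 17.7% was 24.2% with median scaling, 16.9% with scaling to the total and 29.96% as deposited. The causes of these shifts were not tested. No paired analysis was possible because there is only 1 group.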

Other observations

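Tests in this part that were settled after the result was seen are those of muscle fibre share and of fat cells. For connective tissue, the requirement that the result hold without each gene was added after its percentile was seen. Connective tissue genes outside the fixed lists, chosen as a list of 12 (thrombospondins, laminins, integrins, Igfbp6, Fgfr2, Cd44 and Egfr), had mean log2 deviations of 0.31, 0.21, -0.10, -0.62 and 0.20 in mice 1, 3, 4, 5 and 6. The matrix list stood at 0.32, 0.31, -0.39, -0.27 and 0.03 in the same mice. A candidate explanation for the movement of the matrix list is a wider connective tissue programme. The co-variation of the 12 genes was at percentile 98.3 of random lists (permutation test, adjusted p = 0.21 over 12 lists). The percentile was 78.2 without Thbs2 and 58.7 for the median over genes, but 99.1 with genes scaled by their SD. The result thus depends on how genes are weighted, and for unscaled means on 1 dim gene, so the hypothesis stays open.

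A lower share of muscle fibres in the section could also raise matrix genes, and would then raise endothelial markers alike. The 7 endothelial markers, all but Cd34 also in the vascular list, stood at -0.56, 0.05, 0.24, 0.23 and 0.04 in mice 1, 3, 4, 5 and 6, with the same sign as the matrix list in 2 of the 5 mice. In mouse 1 Flt1 had the largest deviation, at -3.00. Tek was at -1.38, Pecam1 at -0.53 and Cdh5 at -0.41, and Cd34 was also below its mean, while Kdr was at 0.02 and Nos3 at 1.49. The lists differed by more than 2 standard errors in only 1 mouse, mouse 5, which is too few to exclude this explanation. Spots next to the matrix probes had a mean deviation whose SD over mice was 0.165 ± 0.0772 (bootstrap SD), near the 0.163 that was set as the limit for an effect of position, so that position also stays open.

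For the fatty acid list, fat cells in the section may contribute. Fabp4 spanned a log2 range of 0.63 over the mice. The mean of the other 7 genes spanned 0.88. The limits for this test were that range and 0.44, so the value decides neither way. Only ranges were compared, which cannot show whether Fabp4 moved with the list. Fabp4 had log2 deviations of 0.28, 0.02, 0.06, -0.01 and -0.35 in mice 1, 3, 4, 5 and 6. It was lowest in mouse 6, as was the list, but highest in mouse 1, where the list was at 0.05. The list was highest in mouse 4, at 0.36. Of other genes that fat cells express, Lpl had log2 deviations of -0.25, 0.58, 0.58, -0.18 and -0.74 in mice 1, 3, 4, 5 and 6, Pparg was above 0 in 4 mice, and Lipe was at or below 0 in all 5. Muscle fibres also express Lpl, and values near the background exclude nothing, so the explanation stays open.

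The values of the 28S ribosomal RNA probe (Rn28s1) carry 2 decimals, where all other probes carry 4. They were 9.42, 8.01, 3.85, 8.95 and 8.40 for mice 1, 3, 4, 5 and 6.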
